A study of Homo sapiens with 6 samples.

How the data were processed

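ATAC-seq libraries of the myeloma cell lines KMS-11, KMS-12 and RPMI8226, 1 with DMSO and 1 with JQ1 for each line, were grouped by the treatment in the labels (6 libraries, 3 per group). The design text of the series speaks of duplicates and of RNA-seq, while the labels list 1 ATAC-seq library per line and treatment. Replicates 1, 2 and 3 stand for KMS-11, KMS-12 and RPMI8226, so that the cell line pairs the DMSO with the JQ1 library. The 3 lines served as the replicates of the treatment, so error is the spread between lines, pooled over all regions where limma was used.

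The authors deposited 1 table of regions with a log2 fold change per line and the number of lines in common. DESeq2 and MACS2 and the builds hg38 and GRCh38.p13 are named, without versions or roles, per the submitters' processing notes. The aligner, read filters, any shift of reads for the transposase, peak settings and scaling of libraries are not given in the sources used here. The header gives neither the log base nor the direction of the fold: base 2 was taken because DESeq2, named for the authors' processing per the submitters' processing notes, reports folds in it, and JQ1 over DMSO was taken from the labels. The number of lines in common, deposited by the authors as another column, is 2 or 3, and was checked to equal the number of lines with a fold at or below -0.5 in all 3838 regions. No fold is above 0, which that rule does not require of the remaining line in regions shared by 2 lines. With 608 of these 2886 folds between -0.1 and 0 and 0 above 0, a filter on sign was assumed, which no source used here states. A test against 0 on regions selected in this way repeats the selection. It gives no read counts, so depth is unknown, no counting interval could be given for a fold, and no count model or other scaling could be run.

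Per region, the mean and SD of the fold over the 3 lines were computed, and limma (version 3.58.1, R 4.3.3) tested the mean against 0 with moderated variances, as written before the data were examined for the case of a table of folds. The prior degrees of freedom were infinite, so every region had the same standard error, 0.262. P-values were adjusted by Benjamini-Hochberg over 3838 regions and called at 0.05. An exact sign-flip test with 3 lines cannot go below p = 0.25, so limma's p-values rest on the spread pooled over regions. For comparison, lines were simulated with sizes drawn independently from the deposited folds of each line and with random signs. They were passed through that selection, at or below -0.5 in at least 2 lines and below 0 in all 3. The sizes came from regions already selected, so the result is not that of unselected noise. On simulated data with 50 changed regions per size among 3838 unselected ones, limma recovered 0% at a log2 fold change of -0.5, 28% at -1, 58% at -1.5 and 80% at -2, with 3 false calls.

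Coordinates are those of the authors' file, on GRCh38 per the submitters' processing notes. Each region was assigned to the gene that contains it, otherwise to the nearest, with protein-coding genes preferred where several contained it, among 20052 protein-coding and 18330 lncRNA genes of the NCBI RefSeq table for GRCh38.p14. That table was used for names, neighbours and distances only. It has no strand, exons or sequence, so regions were not placed in exons, introns or UTRs, distance to a transcription start was replaced by distance to either gene end, and motifs and GC content were not analysed here. In all 3222 genes were assigned, with 2502 regions going to protein-coding and 1336 to lncRNA genes.

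The regions named were fixed by rule before the data were examined: the 12 with the lowest mean among those past the limma threshold with 1 sign in all 3 lines, at most 1 per gene, FLI1, MYC and SMILO, and up to 4 members with a region from each of 17 gene lists. The lists were the title genes, BET inhibitor response, plasma cell identity, B cell program, ETS transcription factors, myeloma translocation and driver genes, NF-kB pathway, interferon response, unfolded protein response, cell cycle, apoptosis, AP-1 and immediate early genes, thioredoxin and redox, Notch pathway, and T and NK cell, myeloid, and stromal and endothelial markers. Of their 306 symbols 1, a second spelling of SMILO, had no match. Part of the interferon response list is not reported here. Lists with at least 2 regions were tested with camera (preset correlation 0.01, and estimated), and all with a region by Fisher's exact test against being shared by 3 lines. In a simulated list of 9 regions lowered by a log2 of -0.5, camera gave an adjusted p of 6.86e-09 and called 0 of 12 other lists.

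Positions were compared with 999 placements in which each region was moved by itself, by 1 to 5 Mb either way along its chromosome. The p-values are two-sided with 0.002 the smallest possible. Such placements scatter neighbouring regions and so treat regions as independent. Where regions cluster, the ranges may be too narrow and the p-values too small. In simulated placements without an effect the share within 1 kb of a gene end was 5.97% (permutation p = 0.64), and with 383 regions moved to gene ends it was 15.5% (p = 0.002). Correlations between lines were set against 199 shuffles, and intervals of differences in width and correlation came from 999 bootstrap samples. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used. Alternatives were a stricter threshold, a minimum size of change, leaving out each line, autosomes, wider regions, other distances and 1 region per gene. Added after seeing the data were the restriction to the 1301 regions whose KMS-11 and KMS-12 values are each shared by fewer than 10 regions, and the comparison of list and gene end positions with shifted placements.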

Results

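Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 3 human multiple myeloma cell lines: KMS-11, KMS-12 and RPMI8226. Each line was treated with DMSO, the solvent control, or with 1 µM JQ1 for 72 h, giving 6 libraries in 2 groups of 3. JQ1 is a small molecule that displaces the BET bromodomain proteins, readers of acetylated histones, from chromatin. The series title links the treatment to the transcription factor FLI1 and to a long noncoding RNA, SMILO, so the question was which regions lost accessibility under JQ1 and whether they lay at these genes. The authors' deposited table held 3838 regions with a log fold change in each line. The log base and the direction are not given by its header: values are read here as log2 of JQ1 over DMSO. Read depth is unknown, and with 1 library per line and treatment a value within a line has no replicate check. A gene name below marks the gene that contains a region or lies nearest to it, since no gene expression was analysed here.

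All 3838 regions of the table had a log2 fold change below 0 in all 3 lines, and the table was taken as selected for this, as described below. With the assumed direction, JQ1 over DMSO, this reads as lower accessibility under JQ1. The values nearest to 0 were -0.0026 in KMS-11, -0.00071 in KMS-12 and -0.00018 in RPMI8226, which 1 library per treatment cannot tell from no change. The median of the mean log2 fold change over lines was -0.71, a JQ1 to DMSO ratio of 0.612. By the authors' deposited table, KMS-12 had the lowest median log2 fold change, -0.79 (quartiles -1.11 and -0.56). KMS-11 followed at -0.71 (quartiles -0.96 and -0.53) and RPMI8226 at -0.61 (quartiles -0.86 and -0.37) in the authors' deposited table. KMS-12 had the most negative value of the 3 lines in 1711 regions (44.6%), KMS-11 in 1232 (32.1%) and RPMI8226 in 895 (23.3%). The lowest single values in the authors' deposited table were -4.17 in KMS-12, -3.04 in KMS-11 and -2.54 in RPMI8226. No test between lines was made, because each line had 1 library per treatment. The share of regions with values repeated in at least 10 regions had the same order, 52.3% in KMS-12, 41.3% in KMS-11 and 7.58% in RPMI8226. With depth unknown, the order of the lines is not read as strength of response.

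**Figure D1:**
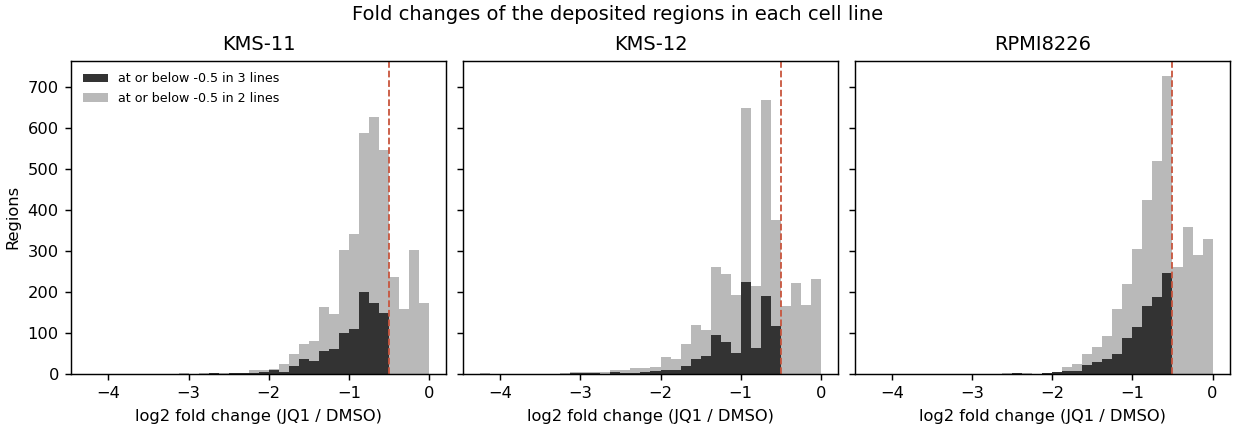
Number of regions (vertical axis) by log2 fold change, JQ1 over DMSO (horizontal axis), in KMS-11, KMS-12 and RPMI8226. Black marks regions at or below -0.5 in 3 lines and grey those at or below -0.5 in 2 lines, stacked, and the dashed line marks -0.5; no region lies above 0, and the medians are -0.71, -0.79 and -0.61.

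The authors' deposited table counted 952 regions (24.8%, Wilson 95% interval 23.5 to 26.2%) as shared by 3 lines and 2886 (75.2%) as shared by 2 lines. That number equalled the number of lines at or below -0.5 in all 3838 regions. Regions shared by 3 lines had a median mean log2 fold change of -0.89 against -0.66 for those shared by 2 lines, and 311 of them (32.7%) had a mean of -1 or lower against 160 (5.54%). The definition itself favours this difference, since a region shared by 2 lines has 1 fold above -0.5. Among the 2886 regions shared by 2 lines, the line that did not reach -0.5 was RPMI8226 in 1235 (42.8%), KMS-11 in 866 (30.0%) and KMS-12 in 785 (27.2%). In these 2886 regions the fold of the remaining line lay between -0.1 and 0 in 608 and above 0 in 0. The table was therefore taken as selected for lower accessibility and for folds below 0 in all 3 lines, although no source used here states the second condition, and regions that rose or stayed level were not used here.

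The lowest mean belonged to a region inside the noncoding RNA gene LINC02740 (chr11:42215956-42216229), at -2.41 ± 2.14 (SD, n = 3 lines). It was low in KMS-11 (-3.04) and KMS-12 (-4.17) and close to 0 in RPMI8226 (-0.03) in the authors' deposited table. Next came regions inside RIMS2, a regulator of exocytosis (chr8:103652237-103652462, -1.86 ± 1.09), CLIP2, a microtubule-binding linker protein (chr7:74382170-74382438, -1.86 ± 0.99), and RAB43, a small GTPase (chr3:129112454-129112739, -1.85 ± 0.87; SD, n = 3 lines each). A region inside AIMP2, a scaffold of the tRNA synthetase complex (chr7:6015824-6016428), reached -1.83 ± 0.68, and one inside COMMD1 (chr2:61978566-61978844) reached -1.71 ± 0.65 (SD, n = 3 lines). The region inside TARDBP, which encodes an RNA-binding protein (chr1:11015782-11016026), averaged -1.72 ± 1.47 (SD, n = 3 lines). In the authors' deposited table its values were -2.16 in KMS-11, -2.92 in KMS-12 and -0.07 in RPMI8226.

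The other regions among the 12 lowest were inside the noncoding genes LOC105376940 (chr3:5754530-5754894, -1.70 ± 0.57), LINC01162 (chr7:20964189-20964497, -1.68 ± 0.54) and LINC01512 (chr6:43910764-43910971, -1.68 ± 0.87; SD, n = 3 lines each). A further region lay 5.23 kb from HROB, a homologous recombination factor (chr17:44136288-44136696, -1.70 ± 0.92, SD, n = 3 lines). The last, on chromosome 17 (chr17:24425367-24425774, -1.71 ± 1.35, SD, n = 3 lines), was 1732 kb from its nearest gene, LOC124904098. The aligner and read filters are not given, so whether reads map uniquely there could not be checked. The mean of LINC02740 was -1.54 and that of TARDBP -1.12 without KMS-12.

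**Figure D2:**
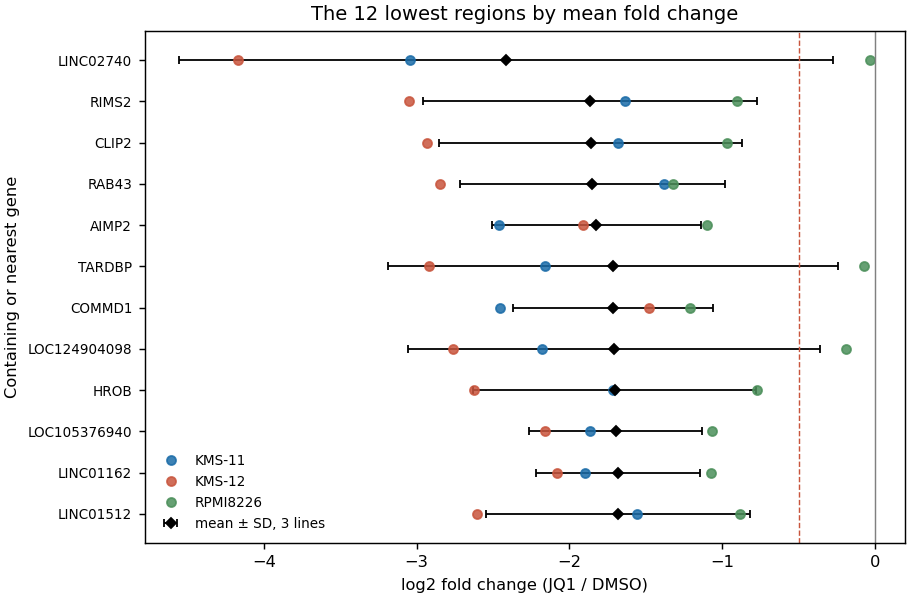
The 12 regions with the lowest mean log2 fold change, JQ1 over DMSO (horizontal axis), named by the containing or nearest gene (vertical axis). Coloured points are the 3 cell lines, black diamonds the mean with bars of 1 SD over lines, the solid line marks 0 and the dashed line -0.5; LINC02740 ranges from -4.17 in KMS-12 to -0.03 in RPMI8226.

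By limma, 3359 of the 3838 regions (87.5%) had a mean below 0 at a Benjamini-Hochberg adjusted p under 0.05, with LINC02740 at 1.57e-16, RIMS2 at 1.73e-09 and TARDBP at 3.53e-08. None was higher. Lines were also simulated with sizes drawn independently from the deposited folds of each line and with random signs. Passed through both conditions of that selection, they gave 3692 regions (96.2%) past the same threshold. Because the sizes were themselves selected, this share is not that of unselected noise. A test against 0 repeats the selection. The count of 3359 and every limma call and adjusted p given here are therefore not taken as evidence of an effect apart from it. This includes those with a line left out. The count fell to 1310 without KMS-11, 1997 without KMS-12 and 2112 without RPMI8226.

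No region was assigned to FLI1, an ETS family transcription factor, to SMILO (LINC00582 in the gene table used) or to MYC, the oncogene best known as a BET target in myeloma. The region nearest to MYC lay 58.4 kb away, inside the noncoding gene PVT1 (chr8:127801329-127801699), with a mean log2 fold change of -0.62 ± 0.12 (SD, n = 3 lines) and a limma Benjamini-Hochberg adjusted p of 0.0269. Its values in the authors' deposited table were -0.71 in KMS-11, -0.66 in KMS-12 and -0.47 in RPMI8226. The region nearest to SMILO was 130 kb away and was assigned to EGLN1, an oxygen-sensing hydroxylase (chr1:231460718-231460904), at -0.87 ± 0.42 (SD, n = 3 lines, limma Benjamini-Hochberg adjusted p = 0.00359). The one nearest to FLI1 was 645 kb away (chr11:128039386-128039993) at -0.57 ± 0.26 (SD, n = 3 lines, limma Benjamini-Hochberg adjusted p = 0.0378). Whether FLI1, SMILO and MYC held accessible regions that did not fall was not analysed here.

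Among 20 plasma cell identity genes, 5 had a region, and all 5 regions passed limma over all regions and 5 adjusted over the list alone. Of all 3838 regions 87.5% passed, which the selection described above brings about. Pass counts here and in the lists below are therefore not read as results about a list. The largest change was at SLAMF7, a plasma cell surface receptor (chr1:160739116-160739463), at -0.97 ± 0.67 (SD, n = 3 lines, limma Benjamini-Hochberg adjusted p = 0.0015). IRF4, a transcription factor that myeloma cells depend on, held a region (chr6:399773-400323) at -0.72 ± 0.50 (SD, n = 3 lines, limma Benjamini-Hochberg adjusted p = 0.013). FCRL5, a receptor of B and plasma cells, stood at -0.72 ± 0.29, the adhesion gene CADM1 at -0.65 ± 0.46, and POU2AF1, a B cell coactivator, at -0.61 ± 0.49 (SD, n = 3 lines each). The SLAMF7 call was lost without RPMI8226 (-0.59), that of IRF4 without KMS-11 (-0.43), and that of FCRL5 without KMS-11 (-0.80) or KMS-12 (-0.55). Those of CADM1 (-0.42 and -0.67) and POU2AF1 (-0.45 and -0.50) were lost without KMS-12 and without RPMI8226. The FCRL5 mean without KMS-11 and the CADM1 mean without RPMI8226 were lower than with 3 lines. In these cases the call was not lost through a weaker mean.

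Of 17 B cell program genes, 4 had a region, and all 4 regions passed limma over all regions (87.5% of all regions did) and 4 adjusted over the list alone. They lay inside BLK, a B lineage kinase (chr8:11530906-11531142, -0.72 ± 0.20), inside CIITA, the activator of MHC class II genes (chr16:10878702-10878989, -0.56 ± 0.31), 58.5 kb from the transcription factor EBF1 (chr5:158636993-158637414, -0.55 ± 0.45) and inside BTK, a kinase of B cell receptor signalling (chrX:101354568-101354954, -0.54 ± 0.42; SD, n = 3 lines each). The BLK call was lost without KMS-11 (-0.61) and that of BTK without KMS-11 (-0.36) or KMS-12 (-0.47). Those of CIITA (-0.73, -0.53 and -0.42) and EBF1 (-0.81, -0.37 and -0.48) were lost without KMS-11, KMS-12 and RPMI8226 alike. Without KMS-11 the means of CIITA and EBF1 were lower than with 3 lines, so a weaker mean was not the reason there. Of 21 genes of myeloma translocations and drivers, IRF4, CCND3 and MAF had 1 region each, and all 3 passed limma, 3 adjusted over the list alone. The region inside CCND3, which encodes a D-type cyclin (chr6:42045691-42045940), was at -0.91 ± 0.57 and that inside MAF, a transcription factor gene (chr16:79593196-79593433), at -0.60 ± 0.30 (SD, n = 3 lines each). The CCND3 call was lost without KMS-11 (-0.62) and that of MAF without KMS-11 (-0.61) or KMS-12 (-0.44). The MAF mean without KMS-11 was no weaker than with 3 lines.

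The lowest region means in the lists were at MAP3K14, of the NF-kB list, and EDEM1, of the unfolded protein response list. By camera neither list as a whole differed detectably from the other regions (Benjamini-Hochberg adjusted p = 0.679 and 0.980). A region inside MAP3K14, the kinase that starts noncanonical NF-kB signalling (chr17:45307513-45307850), was at -1.16 ± 0.37 (SD, n = 3 lines, limma Benjamini-Hochberg adjusted p = 0.000225), and one 21.2 kb from TNFAIP3, an inhibitor of NF-kB (chr6:137904506-137904756), at -0.72 ± 0.41 (SD, n = 3 lines). These were the 2 NF-kB genes of 21 with a region, and 2 passed limma, 2 adjusted over the list alone. In the unfolded protein response list, 5 of 19 genes had 6 regions, and 6 passed limma (87.5% of all regions did), 6 adjusted over the list alone. EDEM1, which sends misfolded glycoproteins to degradation, had a region inside it (chr3:5205378-5205789) at -1.06 ± 0.25 (SD, n = 3 lines, limma Benjamini-Hochberg adjusted p = 0.000591) and another 11.0 kb away (chr3:5230919-5231545) at -0.59 ± 0.12 (SD, n = 3 lines). The stress pseudokinase gene TRIB3 stood at -0.87 ± 0.49, SEL1L, a part of the same degradation route, at -0.73 ± 0.22 and CREB3L2, an ER stress transcription factor, at -0.68 ± 0.34 (SD, n = 3 lines each). The MAP3K14 and first EDEM1 calls held without any line, while that of TNFAIP3 was lost without KMS-12 (-0.49), that of TRIB3 without KMS-11 (-0.72) and that of the second EDEM1 region without KMS-11 (-0.53), KMS-12 (-0.59) or RPMI8226 (-0.65). Those of SEL1L (-0.73 and -0.63), CREB3L2 (-0.74 and -0.49) and ERN1 (-0.52 and -0.68), the other gene of the list with a region, were lost without KMS-11 and without RPMI8226. The CREB3L2 mean without KMS-11 and the second EDEM1 mean without RPMI8226 were lower than with 3 lines.

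In the interferon response list, regions 0.995 kb from OAS1, an antiviral enzyme gene (chr12:112905771-112905967), and inside it (chr12:112925017-112925499) were at -0.82 ± 0.43 and -0.75 ± 0.64 (SD, n = 3 lines each), and both passed limma over all regions. The first OAS1 call was lost without KMS-12 (-0.60) and the second without KMS-11 (-0.58) or RPMI8226 (-0.56). In the AP-1 and immediate early list, FOS was the one gene of 19 with regions, 48.2 kb (chr14:75230035-75230648, -1.01 ± 0.34, SD, n = 3 lines, limma Benjamini-Hochberg adjusted p = 0.00101) and 28.7 kb away (chr14:75249257-75250164, -0.48 ± 0.09, SD, n = 3 lines). The first of the 2 FOS regions passed, also without any line, so 1 passed over all regions and 1 adjusted over the list alone.

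The Notch pathway list had the most regions, 9 at 5 of its 14 genes, and all 9 passed limma, 9 adjusted over the list alone. With 87.5% of all regions past the same threshold, this is not read as a result about the list. MAML3, a coactivator of Notch target genes, had 4 of them, the lowest (chr4:140103711-140104049) at -0.93 ± 0.05 (SD, n = 3 lines, limma Benjamini-Hochberg adjusted p = 0.00225). A region overlapping the end of HES1, a Notch target gene (chr3:194135938-194136216), was at -0.89 ± 0.91, one inside the ligand gene JAG1 (chr20:10644185-10644874) at -0.64 ± 0.33 and one inside NOTCH1 (chr9:136539699-136540145) at -0.60 ± 0.14 (SD, n = 3 lines each). The lowest MAML3 region kept its call without any line. The other 3 did not: the second (chr4:140116498-140116907, -0.71 ± 0.59) was lost without KMS-11 (-0.64) or RPMI8226 (-0.46), the third (chr4:139978669-139979060, -0.57 ± 0.25) without KMS-11 (-0.47) or RPMI8226 (-0.55), and the last (chr4:140186718-140187044, -0.54 ± 0.42) without KMS-11 (-0.77), KMS-12 (-0.35) or RPMI8226 (-0.50; SD, n = 3 lines each). The regions inside MAML2, a further coactivator gene, at -0.54 ± 0.28 (chr11:96016175-96016558) and -0.57 ± 0.29 (chr11:96207536-96207885; SD, n = 3 lines each), were both lost without KMS-11 (-0.42 and -0.42) or RPMI8226 (-0.51 and -0.58). The call of HES1 was lost without KMS-12 (-0.37), that of JAG1 without KMS-11 (-0.81) or RPMI8226 (-0.48), and that of NOTCH1 without KMS-11 (-0.68), KMS-12 (-0.57) or RPMI8226 (-0.55). Without KMS-11 the means of JAG1, NOTCH1 and the last MAML3 region were lower than with 3 lines. Their calls were therefore not lost there through a weaker mean. Placements with each region moved by itself by 1 to 5 Mb gave the list a median of 2 regions (95% range 0 to 5; two-sided permutation p = 0.002, the smallest that the placements can give, Benjamini-Hochberg adjusted p = 0.034 over 17 lists). The 4 MAML3 regions lay within 208 kb, and the placements do not keep such neighbours together, so these p-values may be too small. The placements are genome positions, not accessible regions of these cells, so the Notch count cannot be tied to JQ1. Counted by genes, 5 against a median of 2, the adjusted permutation p was 0.204, and among the 1301 regions with KMS-11 and KMS-12 values shared by fewer than 10 regions the list had 1 region (adjusted permutation p = 1).

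In the remaining lists few genes had a region. ETS transcription factors had 4 of 22, with ELF1 at -0.65 ± 0.16, ETV1 at -0.56 ± 0.50, ETS2 at -0.52 ± 0.20 and EHF at -0.46 ± 0.28 (SD, n = 3 lines each). Of these, ELF1 and ETV1 passed limma over all regions (2) and 0 adjusted over the list alone, and ELF1 was lost without KMS-11 (-0.65) or KMS-12 (-0.57) and ETV1 without KMS-12 (-0.50) or RPMI8226 (-0.34). Of 16 genes of the BET inhibitor response, POU2AF1 and BCL2, an inhibitor of apoptosis, had a region, with BCL2 at -0.44 ± 0.14 (SD, n = 3 lines) not past the threshold, so that 1 passed, 1 adjusted over the list alone. The apoptosis list held BCL2 and PMAIP1, a proapoptotic gene (-0.78 ± 0.81, SD, n = 3 lines), of 19 genes, and 1 region passed, 1 adjusted over the list alone. The PMAIP1 call was lost without KMS-11 (-0.82) or RPMI8226 (-0.35), although without KMS-11 the mean was lower than with 3 lines. Of 27 cell cycle genes, CCND3 passed and the cell cycle inhibitor CDKN1A (-0.51 ± 0.31, SD, n = 3 lines) did not, giving 1 region past limma and 1 adjusted over the list alone. TXNIP, of 14 redox genes, was at -0.46 ± 0.13 (SD, n = 3 lines), with 0 past limma and 0 adjusted over the list alone.

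Markers of other cell types gave few regions. The T and NK cell list of 17 genes had 1 region, inside LEF1, at -0.52 ± 0.29 (SD, n = 3 lines), which did not pass limma over all regions (0) and passed adjusted over the list alone (1), as it did by limma without KMS-12 (-0.69). Of 15 myeloid genes, CSF1R was at -0.74 ± 0.55 and VCAN at -0.65 ± 0.21, and of 14 stromal and endothelial genes PECAM1 was at -0.60 ± 0.16 (SD, n = 3 lines each). The myeloid list had 2 regions past limma and 2 adjusted over the list alone, and the stromal and endothelial list 1 and 1. The calls of CSF1R (-0.72 and -0.48) and VCAN (-0.69 and -0.53) were lost without KMS-11 and without KMS-12, and that of PECAM1 without KMS-11 (-0.58), KMS-12 (-0.52) or RPMI8226 (-0.68). The VCAN mean without KMS-11 and the PECAM1 mean without RPMI8226 were lower than with 3 lines.

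**Figure D3:**
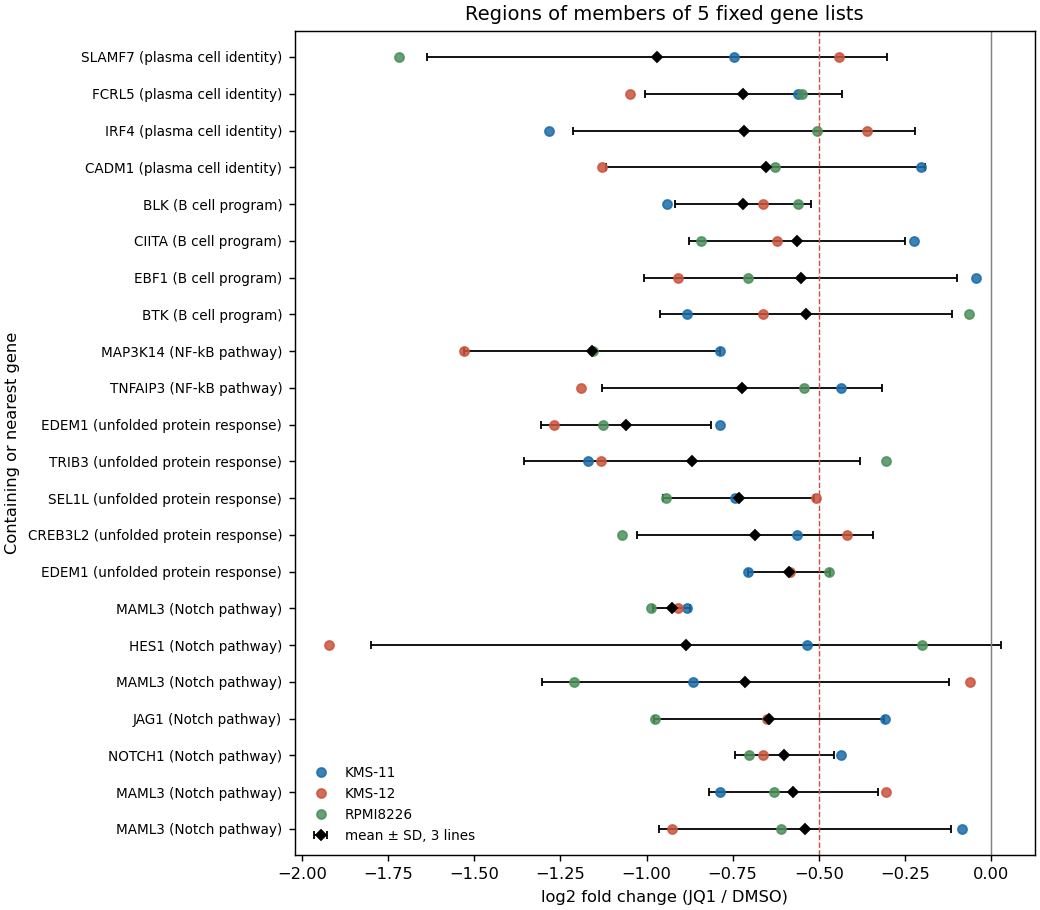
Log2 fold change, JQ1 over DMSO (horizontal axis), of the regions named in 5 fixed gene lists, by containing or nearest gene with the list in parentheses (vertical axis). Coloured points are the 3 cell lines, black diamonds the mean with bars of 1 SD over lines, the solid line marks 0 and the dashed line -0.5; the means run from -1.16 at MAP3K14 to -0.54 at BTK.

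Together the 17 lists held 282 genes, of which 38 had 46 regions, and 38 regions passed limma over all regions, 38 also when adjusted over the list alone with all lists taken as 1. In the whole set 3359 of 3838 regions (87.5%) passed. Shifted placements gave the 282 list genes a median of 26 regions (95% range 16 to 36; two-sided permutation p = 0.002). Each region was moved by itself, so regions clustered at a gene may make this p-value too small. The comparison was with genome positions, not with all accessible regions of these cells, so the excess cannot be tied to JQ1. By camera, limma's test of whether a list's fold changes differ from those of the other regions, 0 of 13 lists passed a Benjamini-Hochberg adjusted p of 0.05, 0 had an unadjusted p under 0.05, and the lowest adjusted p was 0.679 (0.986 with an estimated correlation). Fisher's exact test of list membership against being shared by 3 lines passed for 0 of 16 lists, with 0 at an unadjusted p under 0.05.

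Regions lay closer to genes than shifted placements did. Of the 3838 regions, 2343 (61.0%) overlapped a gene, against a median of 58.0% (95% range 56.4 to 59.5%; two-sided permutation p = 0.004, Benjamini-Hochberg adjusted p = 0.0048). Within 1 kb of either end of a gene lay 319 (8.31%) against 5.76% (5.03 to 6.51%), and within 3 kb 693 (18.1%) against 13.4% (12.4 to 14.4%). A smaller number, 185 (4.82%), were over 100 kb from a gene against 8.47% (7.61 to 9.30%), and 795 (20.7%) had another region within 50 kb against 14.4% (12.9 to 15.7%). Each of these 4 shares had a two-sided permutation p of 0.002, the smallest possible, and a Benjamini-Hochberg adjusted p of 0.003 over 6 measures. Each region was moved by itself, which scatters neighbouring regions. The share with a neighbour within 50 kb therefore shows only clustering relative to scattered positions, and the other p-values take regions as independent. The comparison is with genome positions, not with all accessible regions, and promoters could not be told from gene 3' ends because the gene table used gives no strand.

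**Figure D4:**
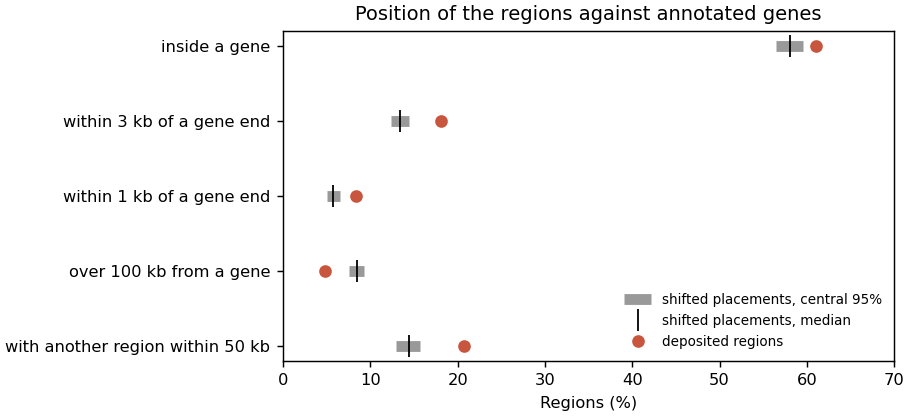
Percent of regions (horizontal axis) in 5 classes of position against annotated genes (vertical axis). Orange points are the deposited regions, black ticks the median and grey bars the central 95% of shifted placements; each point lies outside its bar, as for regions within 1 kb of a gene end, 8.31% against 5.03 to 6.51%.

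Regions near gene ends were not detectably more or less often shared by 3 lines than the rest. Within 1 kb of a gene end 70 of 319 regions (21.9%) were shared by 3 lines, against 882 of 3519 (25.1%) elsewhere (odds ratio 0.841, two-sided Fisher's exact test p = 0.224). Their median mean log2 fold changes were -0.68 and -0.71. Neighbouring regions are not independent.

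The sizes of the changes hardly went together between lines. Across the 952 regions shared by 3 lines, Spearman's rho was 0.0978 between KMS-11 and KMS-12, 0.0783 between KMS-11 and RPMI8226, and 0.00362 between KMS-12 and RPMI8226. Values shuffled within each line gave 95% ranges of -0.0590 to 0.0550, -0.0519 to 0.0616 and -0.0524 to 0.0696 for these pairs, so the pairs with KMS-11 lay above their range and the third pair inside it. Over all 3838 regions the mean rho of the 3 pairs was -0.146, against -0.168 to -0.154 in shuffles that kept the lines in which each region reached -0.5. These correlations are across regions, which are not independent replicates. The shuffles gave the last value the same sign. That all 3838 regions had 1 sign in 3 lines, against 25% by chance in unselected regions, cannot be read as agreement between lines if the table was filtered on sign.

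Many regions had exactly the same fold value, to 9 decimals, as others in that line. In KMS-11 1584 regions (41.3%) had values shared by at least 10 regions, in KMS-12 2007 (52.3%) and in RPMI8226 291 (7.58%). The most shared value in the authors' deposited table was -0.91 in KMS-12, in 213 regions, among them the named regions of EBF1, MAF and MAML3. In KMS-11 it was -0.79, in 178 regions, among them those of MAP3K14, EDEM1 and OAS1, and in RPMI8226 -0.94, in 19 regions including that of SEL1L, by the authors' deposited table. The MAP3K14 and first EDEM1 regions, whose calls held without any line, also had shared KMS-12 values, in 55 and 124 regions. Regions with such values were narrower in KMS-11, with a median of 312 against 473 bp, and in KMS-12, with 343 against 460 bp, while in RPMI8226 the medians were 401 and 391 bp.

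**Figure D5:**
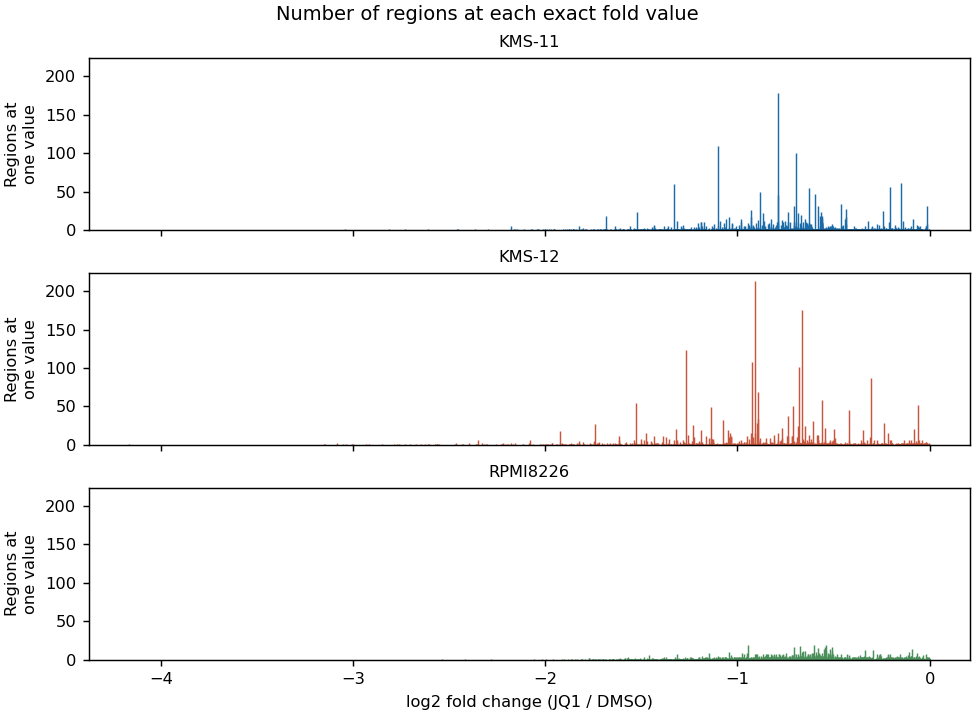
Number of regions at each exact fold value (vertical axis) against that log2 fold change, JQ1 over DMSO (horizontal axis), in KMS-11, KMS-12 and RPMI8226. Each vertical line is 1 value; the tallest hold 178, 213 and 19 regions.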

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

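The alternatives restricted to values shared by fewer than 10 regions, and all comparisons with shifted placements, were chosen after seeing the data. Shifted placements are genome positions, not accessible regions of these cells. The limma count of 3359 regions went to 1614 at an adjusted p of 0.01, to 471 with a mean log2 fold change of -1 or lower, to 1116 among the 1301 regions with values shared by fewer than 10 regions, and to between 1310 and 2112 without 1 line. Fewer regions tested gives the third value, and a larger standard error with 2 lines bears on the last. The median of -0.71 stayed between -0.65 and -0.75 under each alternative run, all on regions that had passed the same selection, which by itself keeps this median below 0. The mean rho of -0.146 was 0.0599 in regions at or below -0.5 in every line, where the selection no longer ties the lines to each other. The Notch count of 9 regions (adjusted p = 0.034) was 5 by genes (adjusted p = 0.204) and 1 among regions with values shared by fewer than 10 regions (adjusted p = 1), where fewer regions were tested. Of the 55 regions named by the rule, 47 passed limma and 17 did so without each line, among them the 12 lowest, whose p-values are the smallest by construction because all regions share 1 standard error. Calls were lost for 23 without KMS-11, 18 without KMS-12 and 17 without RPMI8226. Each fit with 2 lines had its own standard error, so these counts do not rank the lines. The camera count of 0 lists and the gene end odds ratio stayed on their side of the threshold in each alternative run. The count of 3359 is itself from a paired analysis, since each fold is a difference within 1 line, and a fit without that block was not run because it would need values per library. For the same reason other scalings, DESeq2, filters on low counts, pseudocounts, regions above the median mean value and overlaps of peak sets were not run, nor was GC correction, which needs a genome, or camera near gene ends, where lists held too few regions. Unknown depth limits every fold here.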

Other observations

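The tests of different response, of counting noise in KMS-11 and KMS-12 alone, of genome build and of distal regions were chosen after the result was seen, as were the comparisons with shifted placements and the regions and genes singled out here. Among regions shared by 3 lines, some changed by a like amount in each. The strongest by their weakest line lay inside POU2F1, which encodes the octamer-binding partner of the POU2AF1 product (chr1:167264170-167264449, -1.53 ± 0.09), and inside ATP6V1E2, a proton pump subunit gene (chr2:46535309-46535729, -1.49 ± 0.17; SD, n = 3 lines each). RAB43, described above, ranked next by its weakest line but differed more between lines (SD 0.87), and was followed by regions inside ASCC3, a helicase gene (-1.54 ± 0.29), and ALPK1, an innate immune kinase gene (-1.44 ± 0.17; SD, n = 3 lines each).

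The genes with the most regions assigned, 5 each, were DLG2, EMB, ITPR1, NLGN1, SEMA3C and SLC35F3. Of the EMB regions 0 lay inside the gene, and they included regions 772 and 795 kb away. The 4 regions of CXCR5, a chemokine receptor of B cells, lay within 45.2 kb, with a mean of -0.69 ± 0.15 (SD over 4 regions), and the 4 of THSD7B had a mean of -1.05 ± 0.27 (SD over 4 regions). In all 31 genes had 4 or more regions, against a median of 34 in shifted placements (95% range 24 to 43, two-sided permutation p = 0.678). In the 2 Mb beyond MYC, 5 regions lay in or near PVT1, LOC124902020, LINC00824 and CCDC26, 1 of them shared by 3 lines. The same window beyond 20033 protein-coding genes held a median of 3, and 22.0% of these windows held 5 or more. On 7 chromosomes, 15 regions lay over 500 kb from any gene, with a median mean log2 fold change of -0.93, among them 1 on chromosome 1 (chr1:124501650-124502314) at -1.33 ± 1.61 (SD, n = 3 lines). Whether reads map uniquely at these positions could not be checked, so their folds may not reflect accessibility.

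For the fold values repeated exactly in many regions, a candidate explanation is that these regions held few whole reads, so that few ratios were possible. Regions with a value shared by 10 or more were narrower than the others by a median difference of -161 bp in KMS-11 (95% bootstrap interval -175 to -150) and -117 bp in KMS-12 (-130 to -103), as few reads would give. In RPMI8226, with 291 such regions, the difference was 10 bp (-10.5 to 40.0), so width speaks for few reads in KMS-11 and KMS-12 alone. Copied entries would repeat values in every line, but of the 46512 pairs of regions sharing a KMS-11 value 0.112% also shared the RPMI8226 value. No biological explanation was tested for this pattern.

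The sizes of the changes hardly went together between lines. If counting noise in regions with few reads were the reason, wider regions might show a higher correlation. Among regions shared by 3 lines the mean rho was 0.035 in the wider and 0.053 in the narrower regions, a difference of -0.0176 (95% bootstrap interval -0.090 to 0.054). The gain of over 0.1 set beforehand was not met. An upper bound below 0.1 had been set beforehand as the outcome against counting noise, and 0.054 met it. That rule took width as a stand-in for reads. Width did not go with repeated values in RPMI8226, which enters 2 of the 3 pairs. For KMS-11 with KMS-12 alone, looked at afterwards, the difference was 0.0166 (-0.107 to 0.140), too wide to decide. Counting noise was therefore not excluded for that pair. A different response of the 3 lines stays open too and cannot be told apart from variation between libraries, since there was 1 library per line and treatment.

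Regions lay only moderately nearer to gene ends than shifted placements. A different genome build that moved regions as far as the placements do would put the share within the shifted range, whereas 8.31% lay above the highest of the placements, 7.19%. Smaller offsets between builds were not simulated, so a build difference is not excluded by this. Narrow regions, perhaps with few reads, may lower the share: measured from region midpoints, a different measure chosen so that width itself brings no region closer, 8.37% of the wider and 5.90% of the narrower regions lay within 1 kb. The excess over placements by midpoint was 3.59 and 1.15 percentage points, a difference of 2.44 (95% bootstrap interval 0.811 to 4.10). That JQ1 lowered distal regions rather than promoters is a hypothesis that cannot be told apart here, because 0 regions of the table were not lower.

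Flipping the sign of the fold in each line in turn makes 4 splits, too few for a share under 0.05. The real split gave 3359 regions past the limma threshold, and 1 of the 4 splits, the real one, gave as many, the highest other giving 1. Because all folds of the table are below 0, flipping a line had to lower the count, so this contrast tells nothing about chance.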
